A study of Mus musculus with 16 samples.

How the data were processed

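Gene expression was measured in ventricular tissue of 16 female mice on one-colour Agilent arrays. The labels name 4 groups of 4 independent mice: nulliparous and 2-week lactating, each wild-type or Npr1 knockout. Per the labels' protocols, 200 ng of total RNA per mouse was labelled with Cy3 by the Agilent low-input amplification method. The authors scanned each array and extracted spot values with Agilent Feature Extraction 10.7.3.1, per the file headers and processing notes. The deposited scanner values are on a linear intensity scale, 1 value per spot, with background subtraction and spatial detrending within the array and no scaling between arrays, per the file headers.

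The authors also deposited a table of log2 values per probe, whose scale, centring and direction were not given in the sources used here and were found by comparison with the scanner values. Over 17672 bright probes, each column correlated at r = 1 with the log2 scanner signal less the array's 75th percentile and less the mean of the 4 nulliparous wild-type arrays. Positive values are therefore higher than nulliparous wild-type, and none of scale, centring and direction stays unknown. The column medians ran from -0.382 to 0.0318, and the median difference per array from -0.0261 to 0.0187. That table served as an alternative.

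Each array held 62976 spots, of which 59305 were not controls and were averaged into 55681 probes (432 probes had more than 1 spot). Control spots and values marked as outliers by Feature Extraction were left out. Probes were named through their RefSeq accession in a gene table of assembly GRCm38.p6, which named 27793 of 28167 probes with an NM_ or NR_ accession. In all, 28026 probes had a symbol and 27655 (49.7%) had none, 16194 of these being given by a chromosome interval only. The array headers name the mm9 build, so no coordinates are given, and the gene table was used for names, chromosomes and neighbours. Of the 21154 genes, 5681 had more than 1 probe, and the probe with the highest mean over the 16 arrays stood for the gene.

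Values were log2 of the processed signal minus the array's 75th percentile over non-control probes. A gene was kept if its probe was well above background on all 4 arrays of at least 1 group, which left 14063 genes and removed 7091. Of those kept, 12707 were well above background on all 16 arrays and 90 had an outlier value on some array. No probe was saturated. The 75th percentile of the signal was 184 to 246 on nulliparous arrays (326 on knockout replicate 4) and 323 to 405 on lactating arrays. No array was left out. The number of arrays limits the precision of each comparison.

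The 2 slides held 8 arrays each, 2 of every group, and slide 1 and slide 2 were also scans 1 and 2. Every group kept the same array position on both slides, so position within a slide and group cannot be told apart. Slide was tested as a block and each comparison was repeated within each slide.

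A linear model with 4 group means was fitted to all 16 arrays with limma 3.58.1 (lmFit and eBayes, 12 residual degrees of freedom) in R 4.3.3, with the packages jsonlite 2.0.0 and data.table (version 1.17.8). The 5 contrasts were lactation in each genotype, knockout against wild-type in each state, and their interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14063 genes. The 29 gene lists, 18 of pathways, 1 of genes near Npr1 and 10 of cell types, held 553 different measured genes and were tested with camera (two-sided, preset correlation 0.01), adjusted over the 29 lists within a contrast. Camera with an estimated correlation and fry were run beside it. Camera left 1 list member out for an outlier value. Calls within a list were also made with p adjusted over the list alone. Figures were drawn with matplotlib 3.10.9.

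The groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Npr1 on every array, 14 marker genes of hypertrophy, fibrosis and metabolism in each comparison, and, per pairwise comparison, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays of 1 group all lay above those of the other and whose symbol was not a placeholder. It added up to 4 called members of each called list and the 8 called genes with the smallest adjusted p for the interaction. It took 104 genes, a few of which are not reported here.

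Alternatives were normexp background correction (offset 50), quantile normalization, centring on the array median, no filter, a filter on all 16 arrays, the mean of a gene's probes, a fit of only the groups compared, eBayes with trend and robust, array weights, a replicate block, slide as a block, the authors' table, and leaving out each array in turn. The plan named the mean spot signal for normexp, but the files hold the median, which was used. Leaving out arrays for the list tests, and the correlations without nulliparous knockout replicate 4, were added after seeing the data.

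The fitting steps were tested on simulated data made from 13973 genes with 200 changed. At a log2 change of 1, the share of changed genes recovered was 85% for lactation in wild-type, 77% for lactation in knockout, 77% for knockout in nulliparous mice, 76.5% for knockout in lactation and 61% for the interaction. At a log2 change of 0.5 these were 25.5%, 26.5%, 34%, 32% and 7.5%, and at 2 they were 94.5%, 99%, 95.5%, 98.5% and 91%. With each list shifted by 0.5 in simulated wild-type lactation, camera recovered 27 of 29 lists and called 0 when none moved. Each comparison of 4 against 4 had 35 splits of the arrays, and the interaction 100 draws, all but the real data with shuffled residuals. The real grouping was included in each. The other pairwise splits gave medians of 6, 6, 4 and 8 lists, so that 0 is no error rate. Intervals for list medians came from 2000 bootstrap draws.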

Results

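Ventricular tissue of female mice was profiled on one-colour Agilent arrays to ask how the heart's transcripts differ between nulliparous and lactating mice, with and without natriuretic peptide receptor 1. Npr1 encodes the guanylyl cyclase receptor of the heart's natriuretic peptides, and the series concerns the enlargement of the heart that accompanies lactation when signalling through this receptor is lost. The 16 arrays fell into 4 groups of 4 independent mice: nulliparous and 2-week lactating, each wild-type or Npr1 knockout. Each array held 1 mouse, so n = 4 per group throughout, and arrays are named by group and replicate number. The 75th percentile of the signal ran from 184 to 405, and 48.5% to 58.6% of the 55681 probes lay well above background on an array. Of 21154 genes with a probe, 14063 were well above background on all 4 arrays of at least 1 group and were tested. Changes are log2 differences of group means ± standard error (SE), with limma's adjusted p, and the small number of arrays limits their precision. By the rule that named the genes with the largest rises and falls, all 4 arrays of 1 group lay above all 4 of the other for each of them.

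Npr1 itself was read by 1 probe, which was well above background on 9 of the 16 arrays and so failed the filter. Its level, as log2 signal minus the array's 75th percentile, was -4.23, -3.62, -4.11 and -4.47 on nulliparous wild-type replicates 1 to 4 and -4.68, -3.71, -3.53 and -3.93 on the lactating wild-type arrays. It was -3.71, -3.93, -4.15 and -3.87 on the nulliparous knockout arrays and -4.27, -3.84, -3.63 and -4.04 on the lactating knockout arrays. The group means were -4.11 ± 0.36, -3.96 ± 0.50, -3.91 ± 0.18 and -3.94 ± 0.27 (SD, n = 4) in the same order. With no filter, the knockout differed from wild-type by 0.19 in nulliparous mice (adjusted p = 0.778) and by 0.019 in lactating mice (adjusted p = 0.995). A probe this close to background, whose position relative to the deleted part is not known here, checks nothing about the knockout, and the genotypes rest on the labels. In the list of neighbours of Npr1 on chromosome 3, limma called 0 of 42 measured genes between genotypes in either state. At an unadjusted p under 0.05 1 gene was higher and 1 lower in nulliparous mice, and 1 was higher and 3 lower in lactating mice. Adjusted over the list alone, 1 gene was lower in lactating mice (camera's adjusted p of 0.751 and 0.843).

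Arrays separated first by reproductive state. The first principal component held 53.6% of the variance of the 16 arrays, and the lactating arrays lay between 27.64 and 41.93 on it, while the nulliparous arrays lay between -46.91 and -39.33 with a single exception. Nulliparous knockout replicate 4 lay at 14.54. Its mean correlation across genes was 0.9862 with the lactating arrays and 0.9754 with the other nulliparous arrays. Among 1500 genes called and changed by over 1 log2 unit in wild-type lactation, this array carried a median fraction of 0.70 of the change relative to the other 3 nulliparous knockout arrays. Among members of single lists called in wild-type lactation the median fraction was 1.18 for proliferation, 0.856 for macrophage markers, 0.335 for extracellular matrix and 0.277 for the hypertrophy programme, and differences between these were not tested. The array was kept in its labelled group, and its shift from the other 3 is given by each gene group it bears on.

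**Figure D1:**
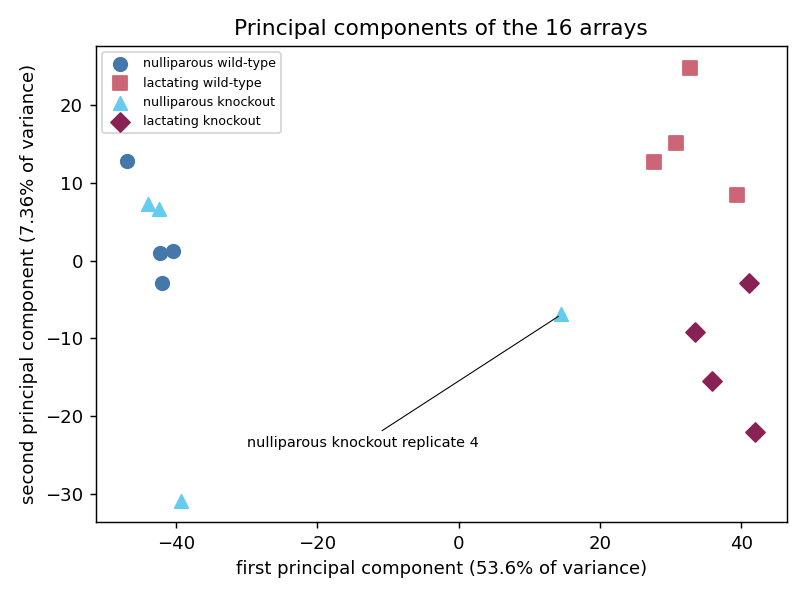
Positions of the 16 arrays on the first principal component (x axis, 53.6% of the variance) and the second (y axis, 7.36%), each point 1 array of 1 mouse, coloured by group. Lactating arrays lie at 27.64 to 41.93 on the x axis, nulliparous knockout replicate 4 at 14.54 and other nulliparous arrays at -46.91 to -39.33.

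Wild-type ventricles were compared to ask which signals differ in lactation when the receptor is present. Nppb, the B-type natriuretic peptide, rose 13.3-fold (3.74 ± 0.39, adjusted p = 4.69e-05). Acta1, the skeletal alpha-actin of the fetal heart, rose 7.92-fold (2.99 ± 0.42, adjusted p = 0.00015). Ccn2, a matricellular growth factor linked to fibrosis, rose 3.75-fold (1.91 ± 0.20, adjusted p = 4.86e-05), and Nppa, the atrial natriuretic peptide, rose 2.34-fold (1.22 ± 0.34, adjusted p = 0.00842). Nr3c2, the mineralocorticoid receptor, fell by 1.49 ± 0.29 on the log2 scale (2.81-fold, adjusted p = 0.000981; 1.85-fold after normexp background correction). In all, limma called 7072 of the 14063 genes (50.3%) at an adjusted p under 0.05, with 4468 higher and 2604 lower in lactation, of which 997 and 504 changed by at least 2-fold.

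The remaining marker genes fixed before the data were examined followed in smaller steps. Ankrd1, a stress-induced ankyrin repeat protein of muscle, rose by 1.14 ± 0.27 (adjusted p = 0.00349), the metalloproteinase inhibitor Timp1 by 1.28 ± 0.28 (adjusted p = 0.00182) and the collagen gene Col1a1 by 0.94 ± 0.24 (adjusted p = 0.00493). Postn, a matrix protein of activated fibroblasts, rose by 0.88 ± 0.28 (adjusted p = 0.0168), a call that ended without nulliparous wild-type replicate 3 (adjusted p = 0.0538) or lactating wild-type replicate 2 (0.0519). Myh6, the main adult myosin heavy chain of the mouse ventricle, fell by 0.39 ± 0.13 (adjusted p = 0.02), which ended without nulliparous wild-type replicate 2 (adjusted p = 0.0631) or lactating wild-type replicate 1 (0.0543) or 3 (0.0644), with quantile normalization (0.853) and with median centring (0.13). Col3a1 (0.71 ± 0.36, adjusted p = 0.118, but 0.0453 with median centring and 0.0371 with array weights), the fetal myosin heavy chain Myh7 (-0.47 ± 0.63, adjusted p = 0.563) and Pdk4, a kinase that restrains glucose oxidation (-0.47 ± 0.46, adjusted p = 0.419), were not called. Il6 was well above background on 4 of the 16 arrays and was not tested.

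Where a probe was well above background on no array of the dimmer group, its fold is a bound, written "at least". The bound is taken against the lowest signal well above background on each such array, for that probe and without normexp. Large rises were those of the trichohyalin-like gene Tchhl1 (at least 35.3-fold, adjusted p = 1.47e-08) and the phospholipid acyltransferase gene Plaat1 (33.9-fold, adjusted p = 9.58e-07). Prim2, a subunit of DNA primase, rose at least 9.81-fold (adjusted p = 8.1e-05), Ogdhl at least 9.05-fold (adjusted p = 0.00373) and mesothelin, Msln, at least 10.3-fold (adjusted p = 0.000133). Serpina3n, an acute-phase protease inhibitor, rose 19.8-fold (adjusted p = 9.37e-05) and the glycogen-binding protein gene Stbd1 19.9-fold (adjusted p = 0.0123). The dimmer nulliparous group was measured above background on 1 of 4 arrays for Serpina3n and on 3 of 4 for Stbd1 and Plaat1. Lactating wild-type replicate 2 held the Stbd1 change down (log2 5.32 without it, against 4.31). Among the falls, the odorant receptor gene Olfr224 was at least 14.6-fold lower (adjusted p = 0.00475) and neuregulin 2, Nrg2, at least 6.75-fold lower (adjusted p = 0.000513). Arc fell by 3.43 ± 0.59 (adjusted p = 0.000412) and the fatty acid elongase gene Elovl7 by 3.38 ± 0.95 (adjusted p = 0.00888). The kallikrein genes Klk1b22 and Klk1b3 fell by 3.39 and 3.32 and the homeobox gene Rhox3a by 3.32, with adjusted p of 0.0156, 0.00379 and 8.1e-05. After normexp all these genes but Arc changed by less than the fold given divided by 1.5. Tchhl1, Plaat1, Serpina3n, Stbd1, Prim2, Ogdhl and Msln were then 6.2-, 12.3-, 3.02-, 6.31-, 2.49-, 2.52- and 2.51-fold higher. The falls were then 3.58-fold for Olfr224, 2.05-fold for Nrg2, 4.06-fold for Elovl7, 4.73-fold for Klk1b22, 3.68-fold for Klk1b3 and 5.88-fold for Rhox3a.

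Of 29 gene lists fixed before the data were examined, camera called 2 in wild-type lactation. In the extracellular matrix list, 23 of 32 measured members rose, 1 fell and 8 were not called (24 and 1 when adjusted over the list alone). Its median change was 0.81 (adjusted p = 0.000599, and adjusted p = 0.849 with an estimated correlation). It was led by fibrillin 1, Fbn1 (2.36 ± 0.30, adjusted p = 9e-05), the collagen cross-linking enzyme Lox (at least 1.74-fold, adjusted p = 6.59e-05) and the microfibril protein Mfap5 (1.37 ± 0.19, adjusted p = 0.000136). In the proliferation list, 22 of 26 rose, 0 fell and 4 were not called by limma (22 and 0 when adjusted over the list alone), with a median of 1.38 (adjusted p = 0.0018, and adjusted p = 0.849 with an estimated correlation). Cyclin B1, Ccnb1, rose at least 4.2-fold (adjusted p = 0.00266), the anaphase activator Cdc20 by 1.42 ± 0.31 (adjusted p = 0.00179) and the replication clamp Pcna by 0.92 ± 0.22 (adjusted p = 0.00331). The mitotic motor Kif11 rose at least 1.3-fold (adjusted p = 0.00318, 2 of 4 lactating arrays above background), but its change was -0.084 after normexp. Normexp also gave 1.36-fold for Ccnb1, 0.086 for Lox, whose call ended (adjusted p = 0.547), and a median of 0.487 for the proliferation list. With members below background in nulliparous mice set to their bound, the medians were 0.77 for matrix and 1.28 for proliferation. On slide 1 and slide 2 the medians were 0.60 and 0.98 for matrix and 0.96 and 1.63 for proliferation, and with slide as a block the adjusted p were 0.00052 and 0.00118.

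The hypertrophy and fetal programme list was not called in wild-type lactation, although 11 of its 18 measured members rose, 3 fell and 4 were not called (12 and 3 when adjusted over the list alone; median 0.56, adjusted p = 0.182, but 0.00795 with no filter on dim probes and 0.00326 with fry). Among the macrophage markers 11 of 19 rose and 1 fell (median 0.72, adjusted p = 0.0788, and 0.015 without nulliparous knockout replicate 4, which enters only the shared spread). It was called with the filter on 16 arrays (0.0145), no filter (0.00143), the mean of a gene's probes (0.0286) and fry (0.00555). Of the 27 lists not called, with adjusted p from 0.0713 to 0.995, 8 had a median, mean and test that differed in sign. Leaving out lactating wild-type replicate 1 gave 4 called lists, with circadian clock (adjusted p = 0.00689) and macrophage (0.0341) added. When each array was centred on its median in place of the 75th percentile, the median change of all genes moved from 0.101 to 0.283 and the split of calls became 6054 higher and 1488 lower (80.3% higher, against 63.2%). With no filter on dim probes the split turned, with 4303 of 9370 calls higher and 5067 lower. The 2 slides, each with 2 arrays of every group, gave 5560 calls (slide 1) and 86 calls (slide 2), the slide block gave 7178, and all 33 called genes taken by the rule had the same sign on both slides.

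Knockout ventricles were compared to ask how the same transition looks without the receptor. Acta1 rose 11.1-fold (3.47 ± 0.42, adjusted p = 0.000437) and Nppb 6.62-fold (2.73 ± 0.39, adjusted p = 0.000484). Postn rose 3.25-fold (1.70 ± 0.28, adjusted p = 0.000753), and C1qa, a complement component made by macrophages, rose 4.01-fold (2.01 ± 0.29, adjusted p = 0.000531). Pdk4 fell 4.41-fold (-2.14 ± 0.46, adjusted p = 0.00264), and Angptl4, a lipoprotein lipase inhibitor under PPAR control, fell 5.83-fold (-2.54 ± 0.40, adjusted p = 0.000649). limma called 6203 genes (44.1%), 3591 higher and 2612 lower, of which 636 and 404 changed by at least 2-fold. Without nulliparous knockout replicate 4 it called 7494 genes, 4306 higher and 3188 lower, 6100 of them shared with the calls over all arrays.

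Among the fixed marker genes, Col1a1 rose by 1.15 ± 0.24 (adjusted p = 0.00222). The inhibitor Timp1 rose by 1.52 ± 0.28 (adjusted p = 0.00122) and Ankrd1 by 1.24 ± 0.27 (adjusted p = 0.00299), and Myh6 fell by 0.63 ± 0.13 (adjusted p = 0.00186, but 0.413 with quantile normalization). Nppa rose by 1.01 ± 0.34 (adjusted p = 0.0266), and this call ended without nulliparous knockout replicate 3 or 4 or lactating knockout replicate 1, 2 or 4 (adjusted p of 0.0685, 0.0723, 0.0548, 0.081 and 0.0569), with array weights (0.149) and with only the groups compared (0.069). Ccn2 rose by 0.55 ± 0.20 (adjusted p = 0.0388), and the call ended without nulliparous knockout replicate 1, 2 or 3 (adjusted p of 0.0823, 0.094 and 0.0879) or lactating knockout replicate 1, 2 or 4 (0.121, 0.0847 and 0.0599), with no filter (0.0656) and with only the groups compared (0.0523). Col3a1 (0.91 ± 0.36, adjusted p = 0.0534) and Nr3c2 (-0.62 ± 0.29, adjusted p = 0.0977) were not called, but were without nulliparous knockout replicate 4 (adjusted p of 0.0349 and 0.0479) and with array weights (0.000681 and 0.00867) or normexp (0.0366 and 0.0486), and Col3a1 also with the filter on 16 arrays (0.0472), median centring (0.0202), the slide block (0.0463) and a trended, robust variance (0.0465). Myh7 was not called either (0.47 ± 0.63, adjusted p = 0.57).

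Other large rises in knockout lactation were those of the gasdermin gene Gsdma (at least 3.56-fold, adjusted p = 0.00229) and the transcription factor Tbx15 (at least 2.42-fold, adjusted p = 0.000471). The division genes Ccnb1, Pimreg and Top2a were 7.24-, 7.07- and 7.5-fold higher (adjusted p of 0.00242, 0.00421 and 0.0214), were above background on 1 of 4 nulliparous knockout arrays, and stood 2.76, 2.91 and 2.75 higher on nulliparous knockout replicate 4 than on the other 3. Without it they were 11.7-, 11.7- and 12.1-fold higher, and after normexp 1.33-, 1.78- and 1.3-fold. The Top2a call ended without nulliparous knockout replicate 1, 2 or 3 (adjusted p of 0.0625, 0.0571 and 0.0553) or lactating knockout replicate 4 (0.0626). Normexp ended the calls of Top2a (adjusted p = 0.238), Gsdma (0.0512, 1.28-fold) and Tbx15 (0.14, 1.2-fold). Among the falls, Bpifb4 was at least 7.89-fold and the defensin gene Defb36 at least 3.1-fold lower (adjusted p of 0.000437 and 0.000791). The sodium pump subunit gene Atp1a4 was called lower (adjusted p = 0.00661), but 2 of 4 lactating arrays were above background and its size depended on the background, with -3.94 over all arrays, -3.26 and -4.74 without lactating knockout replicate 1 or 3 and -1.61 after normexp. The Wnt antagonist Sfrp5 fell 6.85-fold and Zfhx2 6.47-fold (adjusted p of 0.000437 and 0.000543). The probes of Klra1, Tdgf1 and Cd300lf fell 6.63-, 6.37- and 7.38-fold (adjusted p of 0.000471, 0.000437 and 0.000437). Their values ran in parallel over the arrays, so 3 separate falls are not shown. The mean over all probes of Cd300lf was 0.012 higher in lactation. The mean of probes gave 2.22-fold for Zfhx2, 2.08-fold for Tdgf1, 3.15-fold for Defb36 and 3.07-fold for Ccnb1, and normexp 2.96-fold for Bpifb4, 1.71-fold for Defb36, 3.51-fold for Sfrp5 and 2.91-fold for Zfhx2.

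Camera called 10 lists in knockout lactation. Matrix genes rose as a group, with 24 of 32 members up, 0 down and 8 not called by limma (27 and 0 when adjusted over the list alone) and a median of 0.94 (adjusted p = 4.47e-07, and adjusted p = 0.709 with an estimated correlation). Fbn1 rose by 2.37 ± 0.30, the cartilage intermediate layer protein gene Cilp by 2.05 ± 0.30, biglycan, Bgn, by 1.38 ± 0.21 and Mfap5 by 1.23 ± 0.19. Nulliparous knockout replicate 4 stood 0.25 above the other 3 nulliparous knockout arrays in the median of this list, of 1.01 that separated lactating knockouts from those 3, and the median with the member below background at its bound was 0.80. Of 26 proliferation genes 23 rose, 0 fell and 3 were not called (23 and 0 when adjusted over the list alone; median 1.60, adjusted p = 5.92e-06, and adjusted p = 0.709 with an estimated correlation), and replicate 4 stood 1.32 higher, of 1.97. The spindle genes Prc1 and Tpx2 rose by 2.60 ± 0.57 and 2.51 ± 0.55, with replicate 4 higher by 2.58 and 2.45. Without replicate 4 they rose by 3.24 and 3.12, after normexp by 1.31 and 0.62, and with the mean of probes the call of Tpx2 ended (0.83, adjusted p = 0.103). Thymidylate synthase, Tyms, rose by 0.56 ± 0.12, but its change was -0.016 after normexp background correction. With the member below background at its bound, the median of the proliferation list was 1.58, and after normexp it was 0.56.

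Among the cell type lists, those of macrophages and erythroid cells were called higher in knockout lactation and that of adipocytes lower. Of 19 macrophage markers 13 rose, 1 fell and 5 were not called (15 and 1 when adjusted over the list alone; median 1.10, adjusted p = 0.000332, and adjusted p = 0.709 with an estimated correlation). C1qb and C1qc rose by 1.79 ± 0.26 and 1.28 ± 0.18 and the lysozyme gene Lyz2 by 2.49 ± 0.38 (1.73 after normexp). Nulliparous knockout replicate 4 stood 0.79 higher in the median of this list, of 1.20, and 1.73 and 2.26 higher for C1qa and Lyz2. In the interferon response list 8 of 20 rose and 0 fell (the same counts when adjusted over the list alone; median 0.51, adjusted p = 0.00474, and adjusted p = 0.709 with an estimated correlation). These included Irf7 (1.07 ± 0.18), Ifi27l2a (1.43 ± 0.27), Rtp4 (1.07 ± 0.22) and Oas1a (1.24 ± 0.30). Replicate 4 stood 0.36 higher in it, of 0.59. Of 10 erythroid genes 7 rose and 0 fell (the same counts when adjusted over the list alone; median 0.79, adjusted p = 0.00237, and adjusted p = 0.709 with an estimated correlation). They included the globin genes Hbb-b1 (1.55 ± 0.19), Hbb-bt (0.85 ± 0.16) and Hba-a1 (0.81 ± 0.12). Replicate 4 stood 0.30 higher in this list, of 0.87. Adipocyte markers went the other way, with 0 of 9 up and 6 down (0 and 8 when adjusted over the list alone; median -0.97, adjusted p = 0.000718, and adjusted p = 0.709 with an estimated correlation). The lipid droplet gene Cidec was at least 2.34-fold lower, carbonic anhydrase Car3 fell by 2.56 ± 0.34 (2 of 4 lactating arrays above background), adipsin, Cfd, by 1.31 ± 0.35 and Cidea by 0.38 ± 0.10, while replicate 4 stood 0.20 higher in this list. The Cidea call ended with median centring (adjusted p = 0.164) and normexp (0.132). After normexp the list's median was -0.618, Car3 stood at -1.36 and Cidec at -0.715, and Cidec at -1.23 with the mean of probes.

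Of 18 hypertrophy genes 9 rose, 2 fell and 7 were not called (9 and 3 when adjusted over the list alone; median 0.45, adjusted p = 0.0412, and adjusted p = 0.709 with an estimated correlation). Those that rose included the actin-binding Xirp2 (0.92 ± 0.13) and the calcineurin regulator Rcan1 (1.65 ± 0.34). This call ended without nulliparous knockout replicate 4 (adjusted p = 0.38), which stood at -0.13 relative to the other 3 in this list, and without lactating knockout replicate 2 (0.0843) or 4 (0.0532). It also ended with median centring (adjusted p = 0.099) and with the mean of a gene's probes (0.0628). Of 28 genes of fatty acid oxidation 14 fell, 1 rose and 13 were not called (14 and 1 when adjusted over the list alone; median -0.35, adjusted p = 0.000664, and adjusted p = 0.709 with an estimated correlation). They included the mitochondrial enzymes Decr1 (-0.61 ± 0.09) and Acadvl (-0.52 ± 0.09) and the coactivator Ppargc1a (-1.17 ± 0.19), and replicate 4 stood at -0.12, of -0.38. The Decr1 call ended with the mean of probes (adjusted p = 0.317). The median of this list was -0.163 with median centring and -0.226 after normexp. In the contractile and calcium handling list 13 of 20 fell and 4 rose (14 and 4 when adjusted over the list alone), with a median of -0.32 that was 0.015 after quantile normalization, -0.142 with median centring and -0.205 after normexp (adjusted p = 0.0105, and adjusted p = 0.709 with an estimated correlation). Hrc and Myl3 fell by 0.59 and 0.52, Casq2, the calcium buffer of the sarcoplasmic reticulum, rose by 0.76, and replicate 4 stood at -0.21 in this list, of -0.35. The Myl3 call (adjusted p = 0.762) ended with quantile normalization. The list's call ended with quantile normalization (adjusted p = 0.722) and normexp (0.139). In the oxidative phosphorylation list 27 of 70 fell and 10 rose (28 and 10 when adjusted over the list alone), with a median of -0.14 that was 0.042 after quantile normalization, 0.045 after median centring and -0.021 after normexp (adjusted p = 0.00994, and adjusted p = 0.745 with an estimated correlation). The complex I genes Ndufs8 and Ndufa10 rose by 0.85 and 0.78, Ndufa5 and the ATP synthase gene Atp5e fell by 0.47 and 0.50, and replicate 4 stood at -0.052, of -0.14. Quantile normalization ended the calls of Ndufa5 (adjusted p = 0.266) and Atp5e (0.119). The list's call ended with quantile normalization, normexp, median centring, no filter and fry (adjusted p of 0.722, 0.822, 0.199, 0.0535 and 0.179).

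On slide 1 and slide 2, in that order, the list medians of knockout lactation were 0.91 and 0.78 for matrix, 1.91 and 1.35 for proliferation, 1.52 and 0.75 for macrophages and 0.99 and 0.099 for interferon response. They were 0.85 and 0.60 for erythroid genes, -0.90 and -0.87 for adipocytes, 0.30 and 0.56 for hypertrophy, -0.39 and -0.30 for fatty acid oxidation, -0.30 and -0.29 for the contractile list and -0.15 and -0.12 for oxidative phosphorylation. All 10 stayed called with slide as a block (highest adjusted p = 0.0227), and all 60 called genes taken by the rule had the same sign on both slides. Slide 1 gave 6168 called genes and slide 2, which holds nulliparous knockout replicate 4, 0 (limma, against 7388 at an unadjusted p under 0.05 with both slides), and the slide block gave 6374. The split of calls was 57.9% higher, and 5306 higher and 1395 lower (79.2% higher) with median centring. The 19 lists not called had adjusted p from 0.148 to 0.934, and 3 of them had a median, mean and test that differed in sign.

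**Figure D2:**
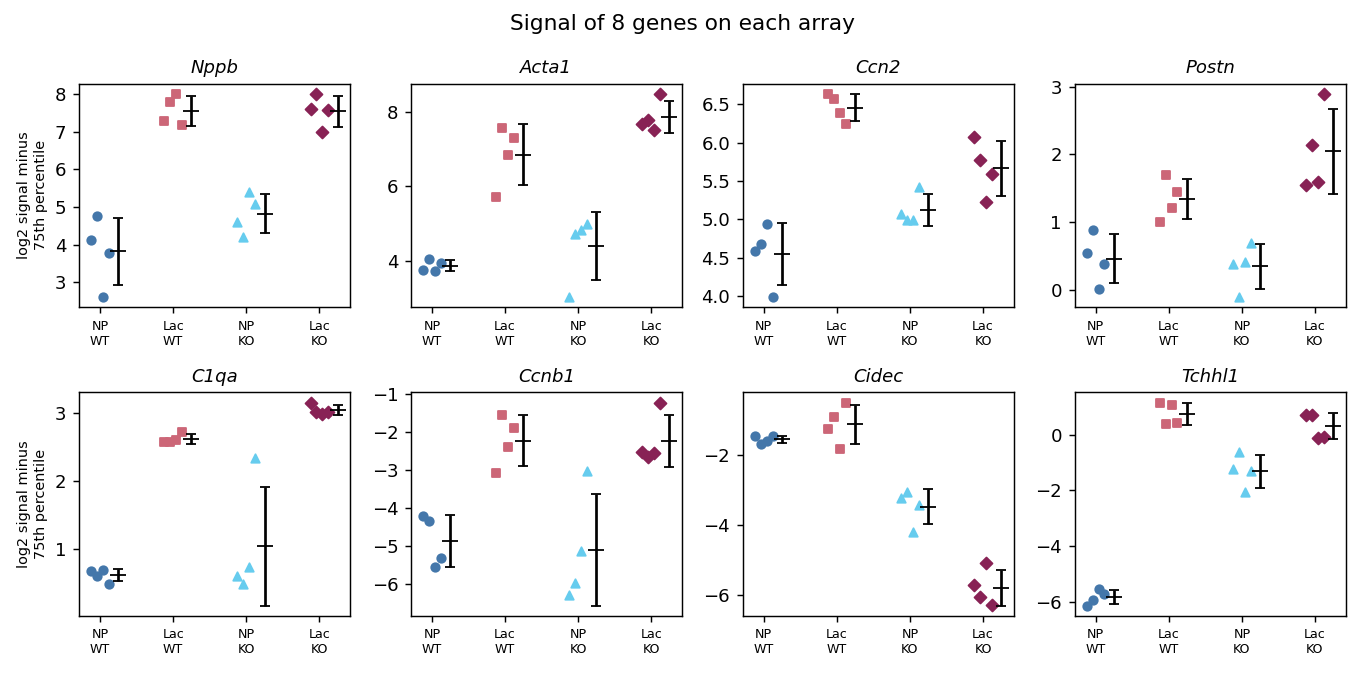
Log2 signal minus the array's 75th percentile (y axis, a separate scale in each panel that does not start at 0) of 8 genes in the 4 groups, each point 1 array of 1 mouse, with a bar at the mean and SD of 4 arrays. Nppb and Acta1 rise in lactation in both genotypes, Ccn2 more in wild-type (1.91 against 0.55, interaction not called). C1qa and Ccnb1 are high on nulliparous knockout replicate 4, and Cidec is lower in knockout than in wild-type lactation.

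The lactation changes of the genotypes ran largely together. Of the genes called in both, 3079 rose in both and 1941 fell in both, against 1141 and 483.7 for independent lists of these sizes, and 11 went opposite ways. Across genes, which are not independent replicates, the changes correlated at r = 0.833 (Spearman's rho = 0.852), and at r = 0.846 without nulliparous knockout replicate 4. The comparisons share no arrays.

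In nulliparous mice, knockout and wild-type hearts were compared to find what the receptor's absence changes before lactation. Tchhl1 was at least 8.53-fold higher in knockout hearts (adjusted p = 2.74e-06), the related hair follicle gene Tchh at least 3.87-fold (adjusted p = 0.000253), and Crispld1 at least 3.06-fold (adjusted p = 6.18e-05). Plaat1 was higher 17.9-fold (4.16 ± 0.32, adjusted p = 1.48e-05; 3 of 4 wild-type arrays above background). These 4 calls stayed whichever of the 8 arrays was left out, but normexp ended those of Tchh (adjusted p = 0.0961, 1.57-fold) and Crispld1 (0.23, 1.39-fold). It gave 2.33-fold for Tchhl1 and 6.68-fold for Plaat1, for which array weights gave 11.1-fold. Adipsin, Cfd, fell by 2.14 ± 0.35 (adjusted p = 0.0282). Cidec fell by 1.92 ± 0.30 (adjusted p = 0.0265, 3 of 4 knockout arrays above background). The growth factor Igf2 fell by 1.09 ± 0.18 (adjusted p = 0.0375). limma called 14 genes in all, 10 higher and 4 lower, against 1214 at an unadjusted p under 0.05, and median centring gave 12 higher and 2 lower (85.7% higher, against 71.4%). The count was 256 with array weights, 7 with normexp, 6 with no filter and 5 with the filter on 16 arrays.

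The riboflavin transporter gene Slc52a3 was at least 2.71-fold higher (adjusted p = 0.0273), and the bicarbonate transporter gene Slc4a8 3.69-fold (adjusted p = 0.0273). The annexin gene Anxa9 was 3.12-fold higher (adjusted p = 0.0417, 3 of 4 wild-type arrays above background) and the lysosomal mannosidase gene Manba 2.28-fold (adjusted p = 0.0273). Dcun1d3 fell by 0.61 ± 0.10 (adjusted p = 0.0377). These 5 calls and those of Cfd, Cidec and Igf2 did not hold when single arrays were left out, although the direction stayed. All 8 ended without wild-type replicate 1 (adjusted p from 0.0821 to 0.0894), 2 (0.0521 to 0.105) or 4 (0.104 to 0.132) or knockout replicate 3 (0.0555 to 0.0619). Between 4 and 7 of them ended without wild-type replicate 3 (0.0722 to 0.0764) or knockout replicate 1 (0.0668 to 0.104), 2 (0.0615 to 0.11) or 4 (0.0539 to 0.0549). No filter ended all 8 (0.0605 to 0.0829), normexp all but Manba and Cfd (0.144 to 0.745), and a fit of only the groups compared those of Slc52a3, Anxa9, Dcun1d3, Cfd and Igf2 (0.143 to 0.453). Normexp gave 1.29-, 2.02- and 1.58-fold for Slc52a3, Slc4a8 and Anxa9. The mean of probes ended the Cidec call (0.16), and median centring those of Igf2 and Dcun1d3 (0.0567 and 0.082). The smooth muscle actin gene Actg2 (0.97) and Gm35438 (1.28), named after their values were seen, were the other calls. The fixed marker genes were not called, with adjusted p from 0.468 for Ccn2 (0.57 ± 0.20) to 0.99 for Myh6, and Nppb stood at 1.00 ± 0.39 (adjusted p = 0.527). The count of calls was 7 without wild-type replicate 1, 2 or 4, 8 without knockout replicate 3, and 18 without knockout replicate 4, 10 of them shared with the 14.

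Camera called 4 lists between genotypes in nulliparous mice. Adipocyte markers were lower in the knockout, with 2 of 9 members called lower and 0 higher (5 and 0 when adjusted over the list alone) and a median of -1.52 (adjusted p = 3.64e-08, and adjusted p = 0.124 with an estimated correlation). Nulliparous knockout replicate 4 stood 0.20 above the other 3 in it. Its median was -0.356 after normexp, and its brightest members were higher in knockout means, without a call: Cidea (5.10 and 5.23 in wild-type and knockout mice), Plin4 (6.75 and 6.97) and Fabp4 (7.90 and 8.06). With the filter on all 16 arrays this list was not called (adjusted p = 0.513). Oxidative phosphorylation genes were higher as a list, 69 of 70 in the mean, with 0 members called by limma, over all genes or adjusted over the list alone, and 15 at an unadjusted p under 0.05 (median 0.13, adjusted p = 3.47e-07, and adjusted p = 0.855 with an estimated correlation). Fatty acid oxidation genes were higher by 0.17 in the median, 25 of 28 in the mean, with 0 called either way and 1 at an unadjusted p under 0.05 (adjusted p = 0.0136, and adjusted p = 0.855 with an estimated correlation). Interferon response genes were lower by a median of -0.20, 17 of 20 in the mean, with 0 called either way and 0 at an unadjusted p under 0.05 (adjusted p = 0.000214, and adjusted p = 0.855 with an estimated correlation). In these lists replicate 4 stood at -0.052, -0.12 and 0.36 relative to the other 3 nulliparous knockout arrays. The fatty acid oxidation call ended without wild-type replicate 2 or 4 (adjusted p of 0.153 and 0.3) or knockout replicate 1 or 2 (0.327 and 0.207), and the interferon call without knockout replicate 2 (0.235). Quantile normalization ended the oxidative phosphorylation and fatty acid calls (adjusted p = 0.123 for each), with an oxidative phosphorylation median of 0.047. Fry ended all but the adipocyte call (0.468 to 0.733). The interferon median was -0.123 with median centring and -0.121 after normexp. Without knockout replicate 4 camera called 11 lists, among them proliferation, lower in the knockout by a median of -0.34 (adjusted p = 1.38e-05), and without wild-type replicate 3 it called 7, with corticosteroid targets (1.88e-06), immediate early genes (0.000426) and prolactin signalling (0.0225) added.

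On slide 1 and slide 2 the medians were -1.35 and -1.60 for adipocytes, 0.074 and 0.19 for oxidative phosphorylation, 0.25 and 0.058 for fatty acid oxidation, and -0.70 and 0.26, with a change of sign, for interferon response. All 4 lists stayed called with the slide block (highest adjusted p = 0.0134). Slide 1 gave 6 called genes, slide 2 gave 12 and the block 14, and the 12 called genes taken by the rule had the same sign on both slides. The 25 lists not called had adjusted p from 0.0788 to 0.947, and 7 of them had a median, mean and test that differed in sign.

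In lactating mice, where the genotypes were compared to find how the hearts differ under the load of lactation, genes of adipocytes were lower in the knockout. Cidec was at least 12-fold lower (adjusted p = 2.45e-06), Cfd fell 18.6-fold (-4.21 ± 0.35, adjusted p = 2.75e-05), adiponectin, Adipoq, 12.9-fold (-3.69 ± 0.34, adjusted p = 6.43e-05) and resistin, Retn, 13-fold (-3.70 ± 0.48, adjusted p = 0.0021). Pck1, the gluconeogenic and glyceroneogenic carboxykinase, was at least 6.95-fold lower (adjusted p = 2.75e-05) and Car3 fell 14.8-fold (-3.89 ± 0.34, adjusted p = 4.92e-05). Adipoq was above background on 1 of 4 lactating knockout arrays, Car3 on 2 and Retn on 3. After normexp Cidec, Cfd, Adipoq, Retn, Pck1 and Car3 fell 2.96-, 11.7-, 2.98-, 3.66-, 2.44- and 4.98-fold. The mean of probes gave 9.1-fold for Cidec. The Retn call ended in a fit of only the groups compared (adjusted p = 0.0545). In the adipocyte list 6 of 9 members fell, 0 rose and 3 were not called by limma (6 and 0 when adjusted over the list alone; median -3.69, -3.58 with the member below background at its bound, and -1.57 after normexp). Its adjusted p was 3.26e-19, and adjusted p = 0.00466 with an estimated correlation, which kept the call. Fabp4, which endothelial cells also express, was chosen after its values were seen and was not called. Its group means were 7.90 and 7.92 in nulliparous and lactating wild-type mice and 8.06 and 7.76 in nulliparous and lactating knockouts.

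limma called 28 genes between the genotypes in lactation, 9 higher and 19 lower (32.1% higher), against 11 and 11 with median centring and 19 and 25 with normexp. With array weights it called 211, with no filter 17 and with the filter on 16 arrays 18. The adenosine receptor gene Adora3 was 3.73-fold higher (1.90 ± 0.22, adjusted p = 0.000546), Hebp2 5.78-fold (2.53 ± 0.27, adjusted p = 0.000355; 1 of 4 wild-type arrays above background) and the prostaglandin transporter gene Slco2a1 2.35-fold (1.23 ± 0.18, adjusted p = 0.00664). St7l rose by 1.10 ± 0.14 (adjusted p = 0.00181), Cdc23, a subunit of the anaphase-promoting complex, by 1.01 ± 0.11 (adjusted p = 0.000497) and Anxa9 by 1.80 ± 0.28 (adjusted p = 0.0141). The syndecan gene Sdc2 rose by 0.70 ± 0.11 (adjusted p = 0.0104) and Cd24a by 0.74 ± 0.13 (adjusted p = 0.0342), and Tox4 fell 12-fold (adjusted p = 0.03), 19.5-fold without knockout replicate 2 and 3.43-fold with the mean of probes. Normexp gave 1.84-fold for Adora3, 1.86-fold for Hebp2 and 1.64-fold for Anxa9. The Cd24a call ended without wild-type replicate 1, 2 or 3 or knockout replicate 3 or 4 (adjusted p from 0.0928 to 0.152), and that of Anxa9 without wild-type replicate 2 or knockout replicate 1 or 4 (0.0523 to 0.0616). The call of Tox4 ended without any array but knockout replicate 2 (0.058 to 0.12), and that of Sdc2 without knockout replicate 4 (0.0536). No filter ended the calls of Cd24a (0.0786) and Tox4 (0.0611), and a fit of only the groups compared those of Cd24a (0.0969), Tox4 (0.108) and Sdc2 (0.0835). The count was 18 without wild-type replicate 2 or knockout replicate 1 and 13 without knockout replicate 4. Markers of hypertrophy and fibrosis were not called, with Acta1 at 1.01 ± 0.42 (adjusted p = 0.484), and Postn at 0.71 ± 0.28 (adjusted p = 0.447). Ccn2 stood at -0.79 ± 0.20 (adjusted p = 0.172, but 0.048 with array weights), Timp1 at 0.61 (adjusted p = 0.532) and Nppb at -0.01 (adjusted p = 0.997).

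Camera called 6 further lists in which no member was called higher or lower over all genes. Macrophage markers were higher by a median of 0.35, 15 of 19 in the mean (adjusted p = 0.00321, and adjusted p = 0.856 with an estimated correlation). Interferon response genes were higher by 0.27, 20 of 20 (adjusted p = 0.000961, and adjusted p = 0.859 with an estimated correlation). Matrix genes were higher by 0.12, 22 of 32 (adjusted p = 0.0404, and adjusted p = 0.859 with an estimated correlation). Contractile genes were lower by a median of -0.12, 19 of 20 (adjusted p = 0.00501, and adjusted p = 0.856 with an estimated correlation). Fatty acid oxidation genes were lower by -0.085, 22 of 28 (adjusted p = 0.00998, and adjusted p = 0.859 with an estimated correlation). Oxidative phosphorylation genes were lower by -0.096, 64 of 70 (adjusted p = 1.85e-05, and adjusted p = 0.859 with an estimated correlation). Adjusted over the list alone, limma called 1 matrix gene lower and 0 members of the other 5 lists. At an unadjusted p under 0.05 it found 3 macrophage, 1 interferon and 3 matrix genes higher and 1 matrix, 0 contractile, 3 fatty acid oxidation and 6 oxidative phosphorylation genes lower. Leaving out wild-type replicate 1 ended the macrophage, interferon, matrix and fatty acid calls (adjusted p of 0.0735, 0.0735, 0.795 and 0.197) and added that of the circadian clock (0.00126, against 0.0557 over all arrays), for 4 called lists. Without knockout replicate 2 the interferon, matrix and fatty acid calls ended (0.112, 0.0603 and 0.0603), and without knockout replicate 4 the matrix and fatty acid calls (0.827 and 0.102). Quantile normalization ended the contractile, matrix, fatty acid and oxidative phosphorylation calls (adjusted p of 0.572, 0.139, 0.122 and 0.455), and median centring the matrix call (0.131). The medians of the contractile and oxidative phosphorylation lists were -0.0193 and -0.0124 after quantile normalization and -0.0439 and -0.0231 with median centring. Median centring also gave -0.012 for fatty acid oxidation and 0.19 for matrix. The hypertrophy list was not called (adjusted p = 0.563), with a median of -0.0044, a mean of 0.070 and a test direction that differed in sign, and the median was 0.026 after quantile normalization and 0.068 after median centring.

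On slide 1 and slide 2 the medians were -3.11 and -3.64 for adipocytes, 0.38 and 0.22 for macrophages, 0.39 and 0.062 for interferon response and 0.13 and 0.11 for matrix. They were -0.14 and -0.12 for the contractile list, -0.19 and -0.020 for fatty acid oxidation and -0.091 and -0.088 for oxidative phosphorylation, and the 7 lists stayed called with the slide block (highest adjusted p = 0.0362). Slide 1 gave 16 called genes, slide 2 gave 4 and the block 30, and the 16 called genes taken by the rule had the same sign on both. The 22 lists not called had adjusted p from 0.0557 to 0.933, and 5 of them had a median, mean and test that differed in sign. Across the reproductive states, which share no arrays, Anxa9 was called higher and Cidec, Cfd and Igf2 lower in the knockout in both, against 0.0064 and 0.0054 genes for independent lists. The changes of all genes correlated at r = 0.223 (rho = 0.166 across genes, and r = 0.151 without nulliparous knockout replicate 4).

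The interaction, which tests whether lactation changed a gene by a different amount in knockout and wild-type hearts, called 13 genes, 3 positive and 10 negative (limma, against 896 at an unadjusted p under 0.05). Tchhl1 was below background on the nulliparous wild-type arrays, so its values depend on the background there. It stood 6.56 higher in wild-type lactation and 1.61 higher in knockout lactation (interaction -4.96 ± 0.41, adjusted p = 8.33e-05). Plaat1 changed by 5.09 and 1.13 (-3.96 ± 0.45, adjusted p = 0.00169) and Tchh, also below background on all nulliparous wild-type arrays, by 3.37 and 0.65 (-2.72 ± 0.37, adjusted p = 0.00932). Cidec changed by 0.44 in wild-type and -2.31 in knockout lactation (-2.75 ± 0.42, adjusted p = 0.018, and 0.0505 without nulliparous wild-type replicate 2). It was below background on all lactating knockout arrays, so its values depend on the background there too. Adora3 changed by -2.36 and -0.33 (2.03 ± 0.31, adjusted p = 0.0161), St7l by -0.999 and 0.65 (1.65 ± 0.20, adjusted p = 0.0024) and Cdc23 by -1.14 and -0.075 (1.07 ± 0.16, adjusted p = 0.0161). The phosphatidylinositol kinase gene Pi4kb changed by 0.88 and -0.34 (-1.22 ± 0.14, adjusted p = 0.00169), and Actg2 by 0.072 and -0.97 (-1.04 ± 0.15, adjusted p = 0.0137). Normexp ended the calls of Adora3 (0.99, adjusted p = 0.149), Cdc23 (0.46, 0.449), Cidec (-0.88, 0.26) and Tchh (-0.71, 0.298) and gave -1.55 for Tchhl1 and -2.55 for Plaat1. None of the fixed marker genes had a called interaction, so their lactation changes are not shown to differ between genotypes. Ccn2 stood at -1.36 ± 0.28 (adjusted p = 0.198, but 0.0426 with array weights), and Nppb at -1.01 ± 0.55 (adjusted p = 0.805). Acta1 stood at 0.48 (adjusted p = 0.914), Postn at 0.82 ± 0.39 (adjusted p = 0.785) and Nppa at -0.21 (adjusted p = 0.954). With array weights the count was 77 and with the filter on 16 arrays 6. Without nulliparous knockout replicate 4 it was 20, including all 13, and with normexp 1 was positive and 9 negative (10% positive, against 23.1%).

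Camera called 9 lists for the interaction, 8 of them with 0 members called by limma, over all genes or adjusted over the list alone. Oxidative phosphorylation genes were more negative in knockout lactation by a median of -0.23, 68 of 70 in the mean (adjusted p = 9.24e-14, and adjusted p = 0.693 with an estimated correlation). Fatty acid oxidation genes were more negative by -0.26, 28 of 28 (adjusted p = 1.35e-05, and adjusted p = 0.693 with an estimated correlation). Interferon response genes were more positive by 0.40, 20 of 20 (adjusted p = 8.41e-09, and adjusted p = 0.693 with an estimated correlation). Adipocyte markers were more negative by -1.91 (1 of 9 called lower over all genes and 5 adjusted over the list alone; adjusted p = 1.79e-08, and adjusted p = 0.133 with an estimated correlation). The oxidative phosphorylation median was -0.0621 after quantile normalization and the adipocyte median -0.88 after normexp. These 4 calls stayed whichever array was left out, and nulliparous knockout replicate 4 stood at -0.052, -0.12, 0.36 and 0.20 in these lists relative to the other 3 arrays of its group. The other 5 called lists had medians of -0.17 (contractile, adjusted p = 0.0317), -0.58 (corticosteroid receptors and targets, 0.0288), 0.15 (fibroblast, 0.0288), 0.066 (macrophage, 0.0335) and 0.33 (erythroid, 0.0103). With an estimated correlation the adjusted p of these 5 was 0.693 for contractile, fibroblast and erythroid lists and 0.724 for the corticosteroid and macrophage lists. The contractile median was -0.0193 after quantile normalization. In the order given, replicate 4 stood at -0.21, -0.48, 0.36, 0.79 and 0.30 in these 5 lists. At an unadjusted p under 0.05 limma found 17 oxidative phosphorylation, 3 fatty acid oxidation, 2 contractile, 3 corticosteroid and 1 erythroid genes more negative, and 3 interferon, 1 fibroblast and 1 macrophage genes more positive.

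Each of these 5 calls ended when certain single arrays were left out. Leaving out lactating wild-type replicate 1 ended the contractile, corticosteroid, fibroblast and macrophage calls (adjusted p of 0.0837, 0.107, 0.107 and 0.205), and nulliparous knockout replicate 2 ended all 5 (0.113, 0.129, 0.113, 0.385 and 0.0547) and left 4 called lists. Lactating knockout replicate 4 ended the contractile, corticosteroid and fibroblast calls (0.0544, 0.0544 and 0.108), nulliparous knockout replicate 1 the contractile, corticosteroid and macrophage calls (0.0757, 0.0817 and 0.237), and nulliparous wild-type replicate 3 the contractile, macrophage and erythroid calls (0.0941 for each). Lactating knockout replicate 2 ended the corticosteroid and erythroid calls (0.0774 and 0.119), nulliparous wild-type replicate 1 the corticosteroid and fibroblast calls (0.136 and 0.0574), and nulliparous wild-type replicates 2 and 4 the corticosteroid call (0.0846 and 0.107). Nulliparous knockout replicate 3 ended the contractile call (0.103), and lactating wild-type replicate 3 and lactating knockout replicate 1 the macrophage call (0.058 and 0.114). On slide 1 and slide 2 the medians were -0.17 and -0.30 for oxidative phosphorylation, -0.44 and -0.041 for fatty acid oxidation, -1.76 and -2.03 for adipocytes, -0.089 and -0.23 for the contractile list, 0.28 and 0.026 for fibroblasts and 0.35 and 0.24 for erythroid genes. The sign differed between slides for interferon response (1.01 and -0.20), corticosteroid targets (-1.21 and 0.10) and macrophages (0.61 and -0.49), and the 9 lists stayed called with the slide block (highest adjusted p = 0.035). Slide 1 gave 6 called genes, slide 2 gave 1 and the block 12, and the 9 genes with a called interaction taken by the rule had the same sign on both slides. The 20 lists not called had adjusted p from 0.0579 to 0.866, among them proliferation (0.0579, called without some single arrays, with 3.71e-06 without nulliparous knockout replicate 4), and 6 of them had a median, mean and test that differed in sign.

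**Figure D3:**
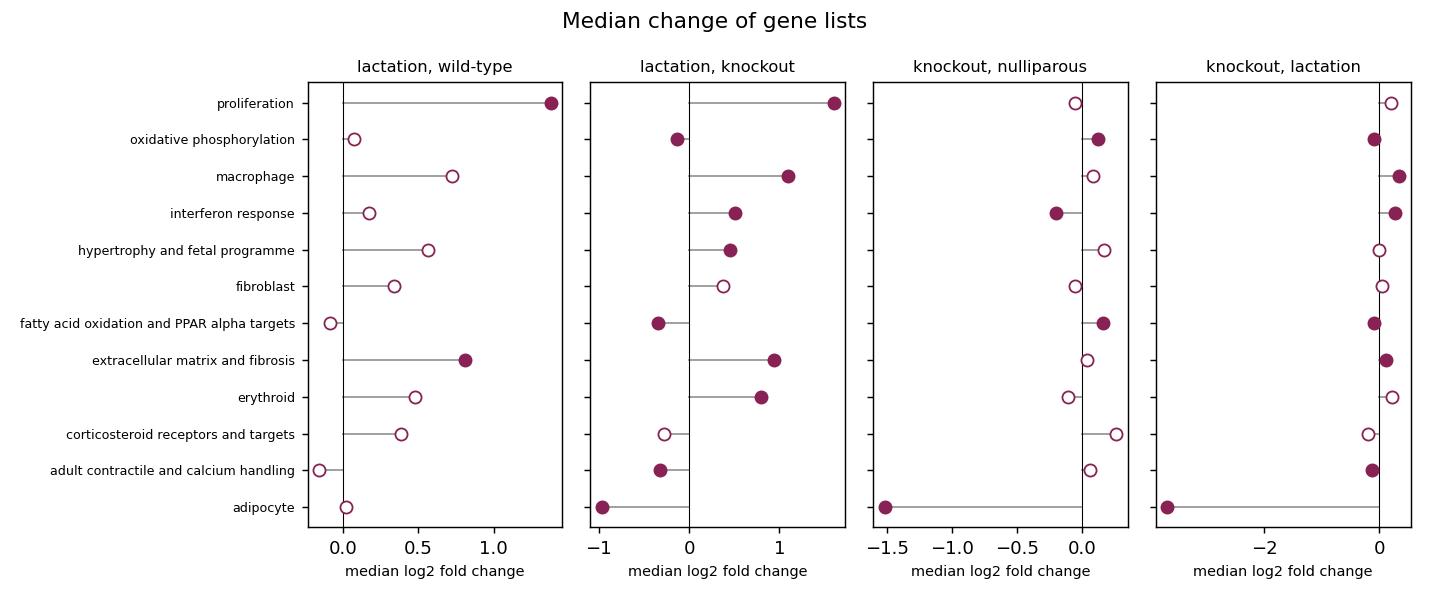
Median log2 change (x axis, a separate scale in each panel) of the measured members of the 12 gene lists called in at least 1 contrast, interaction included, in the 4 pairwise comparisons (y axis), filled where camera's adjusted p was under 0.05. Matrix and proliferation lists lie at 0.81 and 1.38 in wild-type and 0.94 and 1.60 in knockout lactation and adipocytes at -1.52 and -3.69 between genotypes, while the knockout lactation medians of the contractile (-0.32) and oxidative phosphorylation (-0.14) lists turn to 0.015 and 0.042 after quantile normalization.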

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

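The tests of nulliparous knockout replicate 4 as a lactating heart, of chromosome 3, of genes with a wide spread and of the adipocyte markers were chosen after the results were seen. Of 72 groups of 4 arrays tested over 18 measures, 3 had an array whose gap to the nearest other, as a share of the group's range, exceeded Dixon's critical value, which chance does in about 1 in 20, or 3.6. They were the first principal component in nulliparous knockouts (0.921, replicate 4 at 14.54 against -43.94 to -39.33), Acta1 in nulliparous knockouts (0.865, replicate 1 at 3.03 against 4.73 to 4.99) and Col3a1 in lactating knockouts (0.957, replicate 4 at 5.55 against 5.07 to 5.09).

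Nulliparous knockout replicate 4 lay with the lactating arrays. Scanner brightness is argued against: 7 spike-in controls were -0.0665 (log2, 95% interval -0.0932 to -0.0422) relative to the other 3 arrays of its group, while its 75th percentile was higher by 0.618. A probe-specific effect cannot be told apart from a change in RNA, since other probes of the genes that moved by over 1 log2 unit followed the brightest probe by a median ratio of 0.265 (0.181 to 0.421, 160 probes), and in the shared part of the lactation change they followed less than elsewhere (difference -0.394, -0.632 to -0.0938, 157 probes). Among genes changed by over 1 log2 unit in wild-type lactation, other probes followed the brightest by a median ratio of 0.449 (278 probes). The ratio was 0.303 (131 probes) where replicate 4 shared the change and 0.697 (26 probes) where it did not. The lactation folds given therefore hold for the probe that stood for the gene. A lactating heart under a nulliparous label also stays open, since 14 called hypertrophy genes stood at a median fraction of 0.277 of the lactation change (-0.0648 to 0.891), too wide to decide. A biological difference between this mouse and the others was not tested.

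Calls between genotypes lay on chromosome 3, which carries Npr1, more often than other genes did (9 of 38, against 661 of 14025; Fisher's exact two-sided p = 5.63e-05, odds ratio 6.27), and 343 genes had a within-group SD over 0.75, a limit set after exploration. Strain variants carried with the targeted locus that act alike in both states are argued against for 5 of the 9 (Adora3, Pi4kb, St7l, Tchh and Tchhl1), which had a called interaction (ended by normexp for Adora3 and Tchh, adjusted p of 0.149 and 0.298), and cannot be excluded for the 27 calls without one (4 on the chromosome, exact p = 0.0367, and 3 of 22 with exact p = 0.0831 once the adipocyte list is left out). Linked variants that act in one state may contribute: 6 of the 13 interaction calls, these 5 and Bcl2l15, lay on chromosome 3, against 664 of 14050 other genes (exact two-sided p = 1.47e-05, and 0.000144 with the neighbours Tchh and Tchhl1 counted once). Strain background that segregates elsewhere may contribute too: widely spread genes 6 to 100 genes apart deviated together (290 pairs, mean absolute r = 0.401 against 0.296 for shuffled positions, one-sided permutation p = 1e-04, the smallest that the shuffles can give; 298 pairs and 0.408 in a first run that kept pairs with like symbols), although array-level effects can do the same, and dim probes cannot be told apart from it, as 54.8% of the 343 genes were well above background on all arrays of at least 3 groups.

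Adipocyte markers were lower in knockout hearts. A lower yield of all non-muscle cells was not seen but is not excluded, as intervals rest on genes, not mice. In lactating mice the macrophage median was higher by 0.345 (95% interval 0.129 to 0.427, 19 genes). Medians were 0.0483 for fibroblast, 0.108 for endothelial and 0.0063 for smooth muscle markers. Less adipose tissue in the sample cannot be told apart from lower expression in its cells: the deviations of the 9 markers within groups correlated at a mean r of 0.279 (0.212 to 0.35), between the limits set for either reading. None of the abundant members was called. In lactating wild-type and knockout mice Fabp4 stood at 7.92 and 7.76, Plin4 at 6.44 and 6.01 and Cidea at 4.70 and 4.85. A change in fat around the heart with genotype was not tested.

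The lactation change differed between genotypes, by a called interaction, for 13 genes: Tchhl1 (-4.96), Bcl2l15 (-4.21), Plaat1 (-3.96), Pck1 (-2.84), Cidec (-2.75), Tchh (-2.72), Crispld1 (-2.26), Gm3448 (-1.54), Pi4kb (-1.22), Actg2 (-1.04), Cdc23 (1.07), St7l (1.65) and Adora3 (2.03). The sizes for Tchhl1, Tchh and Crispld1 (well above background on 0 of 4 nulliparous wild-type arrays), Bcl2l15 (1 of 4) and Cidec and Pck1 (0 of 4 lactating knockout arrays) depend on the background and are no bounds. Camera's interaction was called for 9 lists, with medians of -1.91 for adipocyte, -0.58 for corticosteroid, -0.257 for fatty acid oxidation, -0.234 for oxidative phosphorylation, -0.167 for contractile, 0.0664 for macrophage, 0.153 for fibroblast, 0.331 for erythroid and 0.402 for interferon response genes. With an estimated correlation none of the 9 was called (adjusted p = 0.133 for adipocyte and 0.693 or 0.724 for the others). Quantile normalization ended the contractile and macrophage calls (adjusted p of 0.942 and 0.146), no filter the macrophage, fibroblast and erythroid calls (0.454, 0.291 and 0.0792) and the filter on 16 arrays the macrophage call (0.249). The mean of a gene's probes ended the contractile, fibroblast and macrophage calls (0.0714, 0.0904 and 0.05), and fry ended all but the adipocyte call.

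Probes without a gene symbol, which the report's comparisons do not use, also carried signal. Of 10474 tested, limma called 4557 in wild-type lactation (43.5%; 1754 higher and 2803 lower), 4500 in knockout lactation (43%; 1216 and 3284), 11 between genotypes in nulliparous mice (10 and 1), 4 in lactating mice (2 and 2) and 4 for the interaction (0 and 4).

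Of 35 splits, only the real one reached the pairwise gene counts. These were 7072 against at most 5 in any other, 6203 against 3927, 14 against 9 and 28 against 2. As 1 of 35 is the least share possible and 4 comparisons were made, this does not exclude chance. The split with 3927 exchanged nulliparous knockout replicate 4 with lactating knockout replicate 1, and that with 9 exchanged nulliparous wild-type replicate 3 with nulliparous knockout replicate 4. For the interaction 2 of 100 draws, the real data among them, reached the real 13, but the other gave 73. Chance is not excluded here either, and why that draw gave 73 was not tested. For the number of called lists chance cannot be excluded: 2, 10, 4 and 7 lists were reached by 33, 8, 22 and 23 of 35 splits (highest others 13, 13, 11 and 14), and 9 for the interaction by 27 of 100 (highest other 15). The splits that followed the slides called 0 genes (limma) and 4, 10, 8 and 10 lists.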

How the results depend on the processing

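The list tests without single arrays and the correlations without nulliparous knockout replicate 4 were chosen after the results were seen. For the genes taken by the rule, 1942 of 2032 values over the other alternatives kept direction and side of the threshold, 74 lost the call, 13 gained it and 3 reversed, and without single arrays 1477 of 1576 kept both, 95 lost the call and 4 gained it. For called lists 246 of 320 kept the call, 73 lost it and 1 reversed, and without single arrays 284 of 328 kept it and 44 lost it. With quantile normalization, with the filter on 16 arrays and without nulliparous knockout replicate 4, the correlation of lactation effects between genotypes (0.8333) was 0.8401, 0.8772 and 0.8458, and the correlation of knockout effects between states (0.2229) was 0.2326, 0.2189 and 0.1506. The reversed values were Cd300lf in knockout lactation with the mean of probes (0.01227), Kif11 in wild-type lactation (-0.08385) and Tyms in knockout lactation (-0.01589) with normexp, and camera's direction for the oxidative phosphorylation list in knockout lactation with quantile normalization (adjusted p = 0.722). In knockout lactation the median also turned for this list with median centring (0.0448) and for the contractile list with quantile normalization (0.0151), while camera's direction stayed. The cause was not tested for any of these or of the counts that follow, except where fewer arrays or genes entered by construction.

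Counts of genes were within 1.5 times in wild-type and knockout lactation for all alternatives. Between genotypes in nulliparous mice the 14 calls became 7 with normexp, 6 with no filter, 5 with the filter on 16 arrays, 256 with array weights and 9 with the replicate block, and 7 to 20 without single arrays. In lactating mice the 28 became 44 with normexp, 17 with no filter, 18 with the filter on 16 arrays and 211 with array weights, and 13 to 34 without single arrays. The 13 interactions became 6 with the filter on 16 arrays and 77 with array weights, and 10 to 20 without single arrays. Array weights gave nulliparous knockout replicate 4 a weight of 0.154.

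Called lists numbered 2 in wild-type lactation, and 0 with an estimated correlation, 4 with normexp, 6 with no filter, 8 with fry and 2 to 4 without single arrays. The 10 of knockout lactation became 0 with an estimated correlation. The 4 between genotypes in nulliparous mice became 0 with an estimated correlation, 2 with quantile normalization, 7 with no filter, 1 with fry and 3 to 11 without single arrays. The 7 in lactating mice became 1, 3 and 2 with an estimated correlation, quantile normalization and fry, and 4 to 10 without single arrays. The 9 of the interaction became 0 and 1 with an estimated correlation and fry, 10 with the replicate block, which added proliferation (adjusted p = 0.0354), and 4 to 12 without single arrays.

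Pairing by replicate number, which follows slide and row, is open. Of pairs sharing a number 8 of 24 correlated over 0.1, against 10 of 72 others (means 0.0482 and -0.016). Of 16 arrays, 7 correlated best with their own number. Genes named as below background have bounds only.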

Other observations

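Named members of the lists in this part were chosen after their values were seen, and no test of an explanation was run. Camera called the circadian list in lactation with median centring (adjusted p of 0.00894 and 0.0369) but not over all arrays with the 75th percentile, while limma called 50.3% of all genes in wild-type and 44.1% in knockout mice. In wild-type mice 3 of 17 members rose and 8 fell (3 and 9 adjusted over the list alone; median -0.79, adjusted p = 0.0713), and in knockouts 2 rose and 7 fell (the same alone; median -0.38, adjusted p = 0.163). Arntl, the activating partner of Clock, rose by 2.91 ± 0.81 (adjusted p = 0.00862) in wild-type and by 2.31 ± 0.81 (adjusted p = 0.0326) in knockout mice. The repressor gene Per3 fell by 2.35 ± 0.49 (adjusted p = 0.00142) and 1.36 ± 0.49 (adjusted p = 0.0363), the output gene Hlf by 1.71 ± 0.35 (adjusted p = 0.00121) and 1.40 ± 0.35 (adjusted p = 0.00579), and Bhlhe41 by 1.48 ± 0.21 (adjusted p = 0.000157) and 0.63 ± 0.21 (adjusted p = 0.0258). The time of day of sampling is not given in the sources used here. Interactions of these genes were not called (adjusted p = 0.656 for Bhlhe41, the lowest of the 4). The list's interaction was at an adjusted p of 0.0579, with 0.026 after normexp and calls at 0.00222 to 0.0495 without any 1 of 6 of the arrays. Between genotypes in lactation it was at 0.0557, with 0.0485 after normexp, 0.0472 with the filter on 16 arrays and 0.025, 0.00126 and 0.0385 without lactating knockout replicate 2 or lactating wild-type replicate 1 or 4.

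Camera did not call the list of glucose genes, but did with normexp (adjusted p of 0.0352 and 0.0323): 12 of 24 rose and 0 fell by limma in wild-type lactation (the same adjusted over the list alone; median 0.25, adjusted p = 0.232), and 10 rose and 3 fell in knockout lactation (11 and 3 alone; median 0.057, adjusted p = 0.326). The phosphoglycerate kinase gene Pgk1 rose by 1.19 ± 0.18 (adjusted p = 0.000219) in wild-type mice and 0.92 ± 0.18 (adjusted p = 0.00167) in knockouts. Of 21 ion channel genes 2 rose and 6 fell in wild-type (adjusted over the list alone 2 and 5; camera's adjusted p = 0.232) and 3 and 3 in knockout lactation (3 and 3; 0.254). The potassium channel subunit Kcnip2 rose by 1.84 ± 0.26 (adjusted p = 0.000133) and 0.99 ± 0.26 (adjusted p = 0.00722), and Kcnj2, the inward rectifier, fell by 1.42 ± 0.16 (adjusted p = 6.38e-05) and 1.04 ± 0.16 (adjusted p = 0.000615). Nulliparous knockout replicate 4 carried a median fraction of 0.584 of the wild-type lactation change among called glucose genes, 0.557 among ion channel genes and 0.272 among clock genes.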
